A study of Homo sapiens with 3 samples.

How the data were processed

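HyperTRIBE RNA sequencing was done on 3 libraries of THP-1 cells, 1 library in each of 3 groups: empty pGK-GFP retrovirus, the hyperactive ADAR catalytic domain alone (ADARcd alone) and DDX41 fused to that domain (DDX41-ADARcd). Cells were harvested for total RNA at day 7 after transduction. Each library was placed in its group by the transgene named in its label.

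The deposited files are 3 lists of A-to-G sites, and their values are counts: per the file headers, the counts of reads with A, T, C and G and the total counts at 1 genome position in each of 2 libraries, with no normalization. The submitters' notes name CASAVA 1.4, FastQC 0.11.7, STAR 2.5 and the mouse build mm10, with no role for each. The site caller, its filters and its annotation are not given in the sources used here. The columns of the lists carry no library name, so the library named first in a list's title was taken as the edited one, and the columns marked gDNA/wtRNA as its control. The reads bear on this: the total at a position was equal between lists for the empty vector at 402 of 402 shared positions, and for DDX41-ADARcd at 3114 of 3114. The values show how the lists were selected. Each listed position has at least 1 edited read in the first library, 0 edited reads and 10 or more reads in the control, and at least 80% A in the control.

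The coordinates were tested against human GENCODE 29 annotation on GRCh38. Of the entries with a gene name in that annotation, 99.6%, 98.9% and 99.8% lay inside the named gene in the lists of ADARcd alone, of DDX41-ADARcd against ADARcd alone and of DDX41-ADARcd against the empty vector, in that order. Of 15631 listed positions on an annotated transcript, 99.9% have A on the transcript. Positions are given on GRCh38. Entries that repeat a position for overlapping genes (134, 184 and 62) were joined into 1 site, which left 6413, 10407 and 3516 sites.

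The editing level is the percent of reads with the edited base (G on the transcribed strand). Intervals of shares are exact Clopper-Pearson 95% intervals, intervals of medians come from order statistics, and a count of 0 is given with a floor of 3 reads of the depth. At a median depth of 286, 30 and 220 reads in the first library and 27, 45 and 30 in the control, an unadjusted p under 0.05 needs levels of 13.6%, 13.3% and 12.7%. A two-sided Fisher's exact test compared edited and other reads at each site with at least 10 reads in each library, with Benjamini-Hochberg adjustment over the sites of a comparison and a threshold of 0.05. It compares those libraries, not the conditions. For DDX41-ADARcd against ADARcd alone the tested positions were the deposited list plus the positions listed for both libraries against the empty vector, since the deposited list holds only positions with 0 edited reads in ADARcd alone. No p across genes was computed.

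Sites were placed in coding exon, 3′ UTR, 5′ UTR, non-coding exon, intron or no gene in that order of priority, measured for their distance to annotated snoRNAs and scaRNAs (500 bases), and given the bases before and after the edited A on the transcript. The weight of editing in a set of sites was estimated with a 2-part mixture of the neighbouring bases of ADARcd sites with 5 or more edited reads and those of other A of the same transcripts, with 200 bootstrap draws. It assumes that the fusion keeps the base preference of ADARcd alone. The 13 gene lists were compared between site lists, and the median level of their sites with 10000 random gene sets of the same size matched on depth in 10 bins, which does not level the depth of the deepest genes. The pattern that defines ribosomal proteins also takes in RPL7L1. Chance overlap between lists was not simulated, because positions without edited reads are not used here.

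Comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names, for each site list, the 10 genes with most sites, the 10 genes with the highest level among sites with at least 20 reads in both libraries, up to 4 members of each gene list with most sites, and DDX41, ADAR and ADARB1. For the test of DDX41-ADARcd against ADARcd alone it names the 10 sites with the smallest p in each direction, 1 per gene. RARS, RPS29, NUCKS1, EEF1G, P4HB, RPSA, MCM4, CALM3, CRCP, ZKSCAN1 and SCARNA21 with its host CHD3 were named after their values were seen. The alternatives were other minimums of reads, edited reads and level, sites of 90% or more left out, mitochondrial sites left out, no edited read in the control, other definitions of overlap, Bonferroni adjustment, reads halved, other distances to snoRNAs, all overlapping regions and subsets of genes. Sites with 3 or more edited reads, and shared sites with 5 or more in ADARcd alone, were added after seeing the data.

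The test was tried on simulated data with the depths of each list, a background of 0.1% and 50 changed sites at each of 4 levels. Of 50 sites simulated at 5%, 10%, 20% and 50%, it called 3, 11, 22 and 45 for ADARcd alone against the empty vector, 9, 10, 23 and 42 for DDX41-ADARcd against ADARcd alone, and 5, 13, 21 and 46 for DDX41-ADARcd against the empty vector. It called 0 of 6212, 8627 and 3312 unchanged sites. These reads were drawn without the selection of the lists for edited reads in the first library and 0 in the control. The 0 calls therefore do not give the error rate at listed sites. The positions listed for both libraries against the empty vector, where all 26 calls of DDX41-ADARcd against ADARcd alone lay, were not simulated. The mixture returned 0.217, 0.21 and 0.188 for a true weight of 0.2, and 0.491, 0.518 and 0.509 for 0.5. Raw reads were not used here. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.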

Results

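The series measured RNA editing in THP-1 cells, a human monocytic leukemia line, by HyperTRIBE. In this method an RNA-binding protein is joined to a hyperactive form of the catalytic part of ADAR, the enzyme that deaminates adenosine to inosine, and RNA near the fused protein is marked by A-to-G changes in its reads. The protein was DDX41, a DEAD-box helicase that is recurrently mutated in myeloid neoplasms. There were 3 libraries, 1 in each of 3 groups: cells transduced with the empty retrovirus, with the catalytic domain alone (ADARcd alone) and with the fusion (DDX41-ADARcd), each harvested for total RNA at day 7. With 1 library per group there was no replicate error, so every comparison is between the reads of libraries and not between conditions.

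The 3 deposited site lists compare ADARcd alone with the empty vector, DDX41-ADARcd with ADARcd alone, and DDX41-ADARcd with the empty vector. Total reads per library were not given in the sources used here, so depth is given per listed position. The median was 286 reads for ADARcd alone and 27 for the empty vector in the first list. It was 30 reads for DDX41-ADARcd and 45 for ADARcd alone in the second, and 220 reads for DDX41-ADARcd and 30 for the empty vector in the last. Every listed position had 0 edited reads in its control, which at the median control depth allows a level of up to 11.1%, 6.67% and 10% in the 3 lists in that order. Editing levels are the percent of reads with the edited base, with exact Clopper-Pearson 95% intervals. Intervals and floors (3 reads of the depth) cover counting error only, since reads from PCR without molecular identifiers are not independent molecules.

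DDX41 itself marked the library that carried the fusion. It had 23 listed positions against ADARcd alone, each in a coding exon, with a median of 236 reads in DDX41-ADARcd and 32 in ADARcd alone. The median read ratio of 6.93 (range 3.59 to 9 over its positions) was the highest of 527 genes with 5 or more listed sites, whose median ratio was 0.659 (5th to 95th percentile 0.488 to 0.876). ADARB1, the gene of the ADAR2 editing enzyme, had the lowest ratio of the 527 genes, 0.217 (range 0.198 to 0.247 over 5 coding positions), with a median of 223 reads in DDX41-ADARcd and 909 in ADARcd alone. ADAR, the gene of the ADAR1 enzyme, had a ratio of 0.714 over 9 positions. The labels name the catalytic domain only as that of ADAR, and not which of these genes it came from. DDX41 and ADARB1 had 0 listed positions in the lists against the empty vector.

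**Figure D1:**
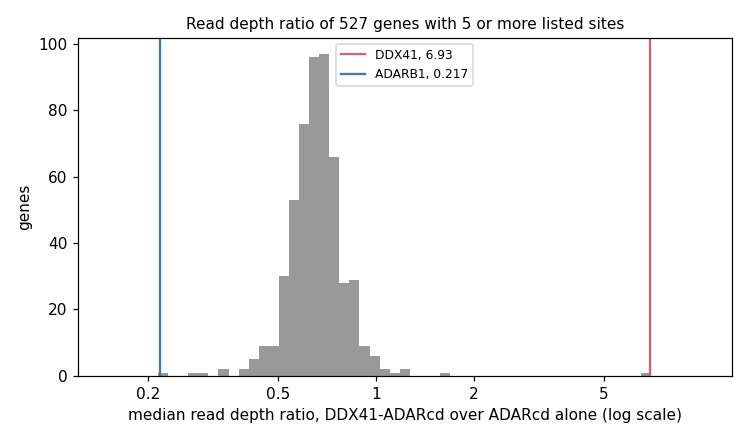
Histogram of the median read ratio of DDX41-ADARcd to ADARcd alone (log scale) over the listed positions of each of 527 genes, 1 library per group. DDX41, at 6.93, and ADARB1, at 0.217, lie at opposite ends of the distribution.

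ADARcd alone edited 10 genes to a level above the empty vector, FTL, RPS3A, PKM, PGK1 and SSR2 at the highest levels. The comparison asks where the catalytic domain edits without a fused protein. FTL, the ferritin light chain, was edited in 816 of 2370 reads (34.4%, 32.5 to 36.4) at position 48966635 of chromosome 19 against 0 of 282 in the empty vector, a floor of 1.06%. RPS3A, a protein of the small ribosomal subunit, was edited at 37.5% (34.6 to 40.4, n = 1104 reads) at position 151104500 of chromosome 4, with a floor of 1.42% in the empty vector. The 3′ UTR of PKM, the pyruvate kinase of glycolysis, reached 41.6% (35.7 to 47.6, n = 279 reads), and that of PGK1, the phosphoglycerate kinase, 29.6% (24.4 to 35.4, n = 280 reads). SSR2, a subunit of the translocon-associated protein complex, reached 47.4% (39.3 to 55.6, n = 154 reads) in its 3′ UTR.

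Of 6412 sites tested between ADARcd alone and the empty vector, 13 in 10 genes passed the two-sided Fisher's exact test at an adjusted p under 0.05. Each position was listed for 0 edited reads in the empty vector, so none could come out lower in ADARcd alone. The test takes no account of that selection, which favours small p. Of these sites, 4 lay in EEF1A1, the elongation factor that delivers aminoacyl-tRNA to the ribosome, with levels from 2.78% to 17.8%. Others were in RPS2 (12.6%), RPS27 (7.39%) and TPT1 (3.30%), besides the 5 genes above. Adjusted p ranged from 6.11e-45 for FTL to 0.0413 for SSR2, and 35 sites had an unadjusted p under 0.05. At reads halved in both libraries, a stand-in for duplicated molecules, 6 of the 13 sites remained below the threshold, and those in PKM, RPS27, PGK1, TPT1 and SSR2 were among the ones that did not. With Bonferroni adjustment 10 remained, without those in PGK1, TPT1 and SSR2. At the median depths of this list, 39 edited reads of 286 (13.6%) are needed for an unadjusted p under 0.05.

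The list held 6413 sites in 1258 genes, and 74.8% of the sites (73.7 to 75.8) rested on 1 edited read. The median level was 0.434% (0.418 to 0.452). The genes with most sites were CAP1 with 90, ACTB with 74, EEF1A1 with 73, PPT1 and TALAM1 with 60 each, YBX1 with 54, MALAT1 with 52, EEF2 with 51, ACTG1 with 50 and COX1 with 46. TALAM1 and MALAT1 lie in the same stretch of chromosome 11, with 666 and 662 reads at their best-supported sites. In each of the 3 lists the TALAM1 site named by the rule fell in no annotated gene. The strand of a site was taken from the base that dominates in the control. Reads of TALAM1 and MALAT1 therefore cannot be told apart. ACTB and ACTG1 encode the cytoplasmic actins, and CAP1 encodes an actin-binding protein. Their best-supported sites were low: CAP1 had 0.867% (19 of 2192 reads, 0.523 to 1.35) and ACTB 0.84% (23 of 2737 reads, 0.533 to 1.26). Among other sites with high levels and at least 20 reads in both libraries were those in SRP14, of the signal recognition particle (22.2%, 16.7 to 28.5), RPL15 (15.3%, 10.6 to 21.0) and HLA-B, an MHC class I heavy chain (12.9%, 8.69 to 18.2). In the Fisher's exact test these 3 sites did not pass.

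**Figure D2:**
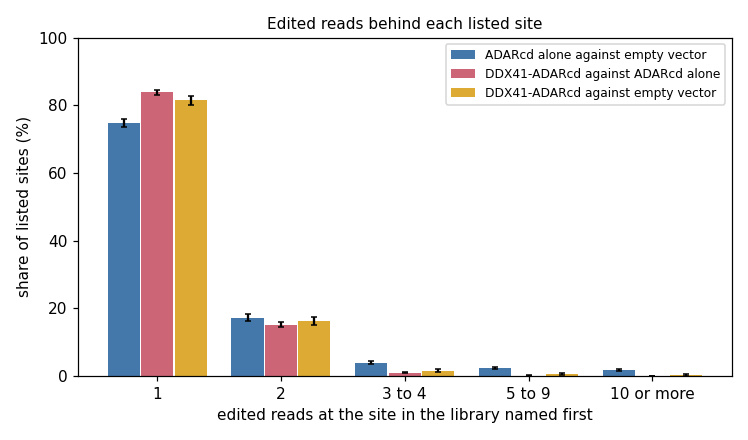
Percent of the sites of each deposited list by the number of edited reads at the site, with exact 95% intervals. Sites with 1 edited read make up 74.8%, 83.9% and 81.5% of the lists, in the order of the legend.

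DDX41-ADARcd had no site that passed the test against the empty vector. The comparison asks which RNAs carry edits in cells with the fusion. The sites with the smallest p were in RARS, the arginyl-tRNA synthetase, with 19 of 28 reads (67.9%, 47.6 to 84.1), in the 3′ UTR of RPL7L1, a ribosomal protein-like gene, with 16 of 69 reads (23.2%, 13.9 to 34.9), and in HLA-B with 19 of 146 reads (13.0%, 8.02 to 19.6). All 3 sites were listed for ADARcd alone too, at 63.9% (46.2 to 79.2), 35.4% (25.1 to 46.7) and 12.9% (8.69 to 18.2). A cluster in the 3′ UTR of SPN, the leukocyte sialoglycoprotein CD43, reached 16.9% (11 of 65 reads, 8.76 to 28.3) in DDX41-ADARcd and 24.2% (30 of 124 reads, 17.0 to 32.7) in ADARcd alone.

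The list held 3516 sites in 957 genes, 81.5% of them (80.2 to 82.8) on 1 edited read, with a median level of 0.515% (0.488 to 0.546). Most sites lay in ACTB with 68, CAP1 with 58, EEF1A1 with 45, MALAT1 with 41, YBX1 with 37, TALAM1 with 36, the mitochondrial ND4 and ND5 and the gene PPT1 with 27 each, and HNRNPU with 25. After HLA-B, the highest levels with at least 20 reads in both libraries were 4.17% in DYNC1H1 (1 of 24 reads, 0.105 to 21.1), 3.51% in the snoRNA host RNA GAS5 (4 of 114 reads, 0.964 to 8.74) and in PTP4A2 (2 of 57 reads, 0.428 to 12.1), and 3.17% in ATF4 (4 of 126 reads, 0.872 to 7.93). SRP14, SCAF11, SF3B1, IMPDH2 and PRRC2C followed, from 3.16% down to 2.74%. The Fisher's exact test covered 3512 sites. Unadjusted p was 0.000391 for RARS, 0.0341 for RPL7L1 and 0.0467 for HLA-B, the 3 sites below 0.05, each with an adjusted p of 1. At the median depths of this list 28 edited reads of 220 (12.7%) are needed for an unadjusted p under 0.05, and 11 sites had a level of 10% or more.

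Sites in FTL, RPS3A, EEF1A1 and other genes that ADARcd alone edited strongly had lower editing in DDX41-ADARcd. The comparison asks which edits follow from the DDX41 part of the fusion. Of 9227 positions with reads of both libraries, 26 sites in 20 genes passed the two-sided Fisher's exact test, all of them lower in DDX41-ADARcd. All 26 lay among the 400 tested positions listed for both libraries against the empty vector. The other 8827 were listed for 0 edited reads in ADARcd alone, so none of them could come out lower. Adjusted over the 400 positions alone, 32 sites in 25 genes passed, all of them lower. The 26 sites had a median fold of 19.4 (quartiles 10.8 to 35.7, n = 26 sites). Selection by the test raises that fold: the median was 9.09 over the 37 shared sites with 10 or more edited reads and 5% or more in ADARcd alone, 4.60 over the 78 with 5 or more edited reads, and 0.803 over all 402. FTL fell from 34.4% to 0.704% (11 of 1563 reads, 0.352 to 1.26; adjusted p 6.83e-185), and RPS3A from 37.5% to 0.39% (3 of 769 reads, 0.0805 to 1.14; adjusted p 4.27e-103). EEF1A1 fell at 4 sites, most strongly supported at position 73518527 of chromosome 6, from 17.8% (16.2 to 19.4) to 0.403% (0.162 to 0.829), with an adjusted p of 5.62e-92.

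Cytosolic ribosomal proteins, a list fixed in advance, had 11 of the 26 lower sites in 8 genes: RPS2 with 3, RPS3 with 2, and RPS3A, RPS27, RPS27A, RPS29, RPSA and RPL15 with 1 each. Adjusted over the list alone, 11 of the 520 sites of that list passed as well. In the list of DDX41-ADARcd against the empty vector, which holds all 26 lower sites, sites of these genes had a median of 616 reads in DDX41-ADARcd, against 220 over all sites. Over the 402 sites listed for both libraries that median was 440 reads, and the depth of the ribosomal sites among them was not computed. Greater depth lets the test pass smaller differences, so the count does not show that ribosomal genes lost more editing than others. The elongation factor genes EEF1A1, EEF1G and EEF2 fell too, EEF2 from 3.71% to 0.38%. PKM fell from 41.6% to 1.79% (0.37 to 5.13), SSR2 from 47.4% to 1.30% (0.0329 to 7.02), and NUCKS1, a nuclear DNA-binding protein, from 17.4% to 1.20% (0.145 to 4.26). SRP14 fell from 22.2% to 3.16% (adjusted p 2.93e-05). P4HB, the protein disulfide isomerase, MCM4, of the replicative helicase, CALM3, a calmodulin gene, and TPT1 completed the genes, and the largest adjusted p of the 26 was 0.042 for CALM3. The sites in P4HB, RPSA, RPL15, MCM4, EEF2 and CALM3 no longer passed with Bonferroni adjustment (20 sites left) or with reads halved (19 left), and EEF1G not with reads halved (adjusted p 0.116). For RPSA and RPL15, the ribosomal genes among them, the Bonferroni p was 0.11 and 0.171. The fold in read depth at the 26 sites had a median of 1.42 and a maximum of 2.

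**Figure D3:**
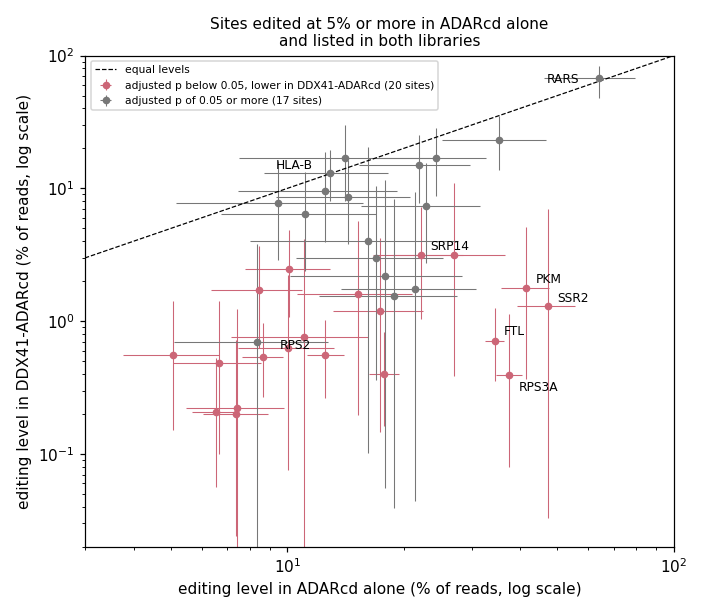
Editing level in DDX41-ADARcd against ADARcd alone (percent of reads, log scales) at the 37 sites listed for both that had 10 or more edited reads and a level of 5% or more in ADARcd alone. Bars are exact 95% intervals of each library's reads, and 34 of the 37 sites lie below the line of equal levels.

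No site was higher in DDX41-ADARcd than in ADARcd alone by the test, and 40 sites were higher at an unadjusted p under 0.05. The most strongly supported was in the 3′ UTR of RNF24, a RING finger gene, at position 3929317 of chromosome 20, with 10 of 17 reads (58.8%, 32.9 to 81.6) against 0 of 17, a floor of 17.6%, and an adjusted p of 0.0977. The 3′ UTR of BPNT1, on the list of endogenous A-to-I substrates, had 6 of 11 reads (54.5%, 23.4 to 83.3) against 0 of 13. Smaller numbers were seen in APOL6 (6 of 19 reads), GM2A (5 of 28), PGAM5 (4 of 22), SLC35E2B (4 of 15), ST3GAL3 (4 of 14), SPN (4 of 31), LYST (4 of 94) and the snoRNA host RNA LRRC75A-AS1 (4 of 220). Adjusted over the 8827 positions of the deposited list alone, the smallest adjusted p was 0.541. Positions edited in ADARcd alone with no edited read in DDX41-ADARcd carry no DDX41-ADARcd reads in the lists, so the count of lower sites leaves them out. Positions edited in both libraries were tested only where the empty vector had 10 or more reads and 0 edited reads. Other positions edited in both could not come out as higher or lower.

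The deposited list of DDX41-ADARcd against ADARcd alone held 10407 sites in 4036 genes, with a median level of 3.70% (3.57 to 3.85). Sites with 1 edited read made up 83.9% (83.2 to 84.6), and 8 sites had 5 or more. These 8 were in RNF24, BPNT1, APOL6, GM2A, the 3′ UTR of CRCP (5 of 19 reads), an intron of PRR11 (6 of 9 reads) and DDX41, where 8 of 183 reads (4.37%, 1.91 to 8.43) and 8 of 242 reads (3.31%, 1.44 to 6.41) were edited. The genes with most sites were CAP1 with 80, NFYC with 58, ACTB with 48, MALAT1 with 45, LYST with 43, TRIT1 with 42, TALAM1 with 40, SPN with 36, EEF1A1 with 35 and YBX1 with 34. Among sites with at least 20 reads in both libraries the highest levels were 18.2% in PGAM5 (5.19 to 40.3), 17.9% in GM2A (6.06 to 36.9), 16.7% in GINS1 (4.74 to 37.4), 14.3% in AP1S3 (3.05 to 36.3) and 13.6% in TBC1D10B (2.91 to 34.9). SPN, TRIT1, PRR11, IL17RA and MAGT1 followed, down to 10%.

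The lists shared sites by construction, since they share libraries. Of the 3516 sites of DDX41-ADARcd against the empty vector, 3114 (88.6%) were also listed against ADARcd alone and 402 (11.4%) were also listed for ADARcd alone. In the list of DDX41-ADARcd against the empty vector, all 30 sites with 5 or more edited reads were sites of ADARcd alone, against 8.73% (7.72 to 9.82) of those with 1. FTL, RPS2, EEF1A1, ACTB, SPN and ND4 were among the 30. The 8 sites with 5 or more edited reads in the list against ADARcd alone could not be, since that list holds only positions with 0 edited reads there. Of the 61 sites with 10 or more edited reads and a level of 5% or more in ADARcd alone, 37 were listed for DDX41-ADARcd. Their median level was 15.3% in ADARcd alone and 1.75% in DDX41-ADARcd, a median fold of 9.09. Over all 402 shared sites the median difference was 0.0218 points higher in DDX41-ADARcd, 243 sites being higher and 159 lower. At 155 of them both libraries had 1 edited read, and DDX41-ADARcd had the lower depth, a median of 513 against 717 reads. Over the 78 shared sites with 5 or more edited reads in ADARcd alone, chosen after the values were seen, the difference was -2.89 points (-6.17 to -2.34).

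The 13 gene lists fixed in advance were compared between the site lists by the share of listed genes they held. Cytosolic ribosomal proteins made up 8.15% of the genes of DDX41-ADARcd against the empty vector (78 genes), 6.36% of those of ADARcd alone (80 genes) and 1.96% of those of DDX41-ADARcd against ADARcd alone (79 genes). In the first of these the members RPL13A and RPL4 had 16 sites each, and RPS29 and RPS3A had 14. Their median level stood at percentile 83.9 of 10000 random gene sets matched on depth in DDX41-ADARcd against the empty vector (0.187%) and 93.7 in ADARcd alone (0.148%). In DDX41-ADARcd against ADARcd alone no percentile is given, because the matching left these genes at a median of 589 reads a site against 301 in the random sets, and the level of a site with 1 edited read is set by its depth. The test against the empty vector called 4 members for ADARcd alone, RPS2, RPS3A and RPS27 among them, and 0 for DDX41-ADARcd. Adjusted over the list alone, the counts were 5 sites of the same 4 members for ADARcd alone and 0 for DDX41-ADARcd.

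Genes that host snoRNAs, the guide RNAs of ribosomal RNA modification, made up 2.51% of the genes of DDX41-ADARcd against the empty vector (24 genes), 2.38% for ADARcd alone (30 genes) and 1.16% of those against ADARcd alone (47 genes). HSPA8, a chaperone, had 18 sites in DDX41-ADARcd against the empty vector, NCL, the nucleolin gene, 17, TPT1 16 and EEF2 15. TPT1 and EEF2 were the 2 members that fell against ADARcd alone, and TPT1 was the member that passed for ADARcd alone against the empty vector, with the same counts adjusted over the list alone. Ribosome biogenesis and nucleolar proteins had 9 genes (0.94%) against 7 (0.556%) for ADARcd alone and 36 (0.892%) against ADARcd alone, among them NCL with 19 sites, NPM1, the nucleophosmin gene, with 9, and GNL3L with 22. Spliceosome components had 23 genes (2.40%), 31 genes (2.46%) and 51 genes (1.26%) in the same order, with HNRNPU, HNRNPA2B1 and HNRNPA1, all nuclear RNA-binding proteins, carrying most sites against the empty vector. No site of these 2 lists passed a test, over all sites or adjusted over the list alone.

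DExD/H helicases had 6 genes with 9 sites in DDX41-ADARcd against the empty vector, 5 genes for ADARcd alone and 18 against ADARcd alone, where DDX41 had 23 of the 70 sites. DHX9, a nuclear RNA helicase, had 9 of 121 reads edited in ADARcd alone (7.44%, 3.46 to 13.7). Genes of the cGAS-STING and interferon response had 6, 6 and 23 genes, and SAMHD1, a dNTP hydrolase, had 4 of 98 reads edited in DDX41-ADARcd (4.08%, 1.12 to 10.1) against 1 of 208 in ADARcd alone. R-loop and DNA damage genes had 9, 11 and 33 genes, with PRKDC and XRCC5 of the DNA end-joining machinery among them. Myeloid leukemia genes had 7, 9 and 24 genes. The transcription factor gene MYB had 27 sites against ADARcd alone. These 4 lists had no site that passed, over all sites or adjusted over the list alone.

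Endogenous A-to-I substrates, genes known to be edited by the cell's own ADAR enzymes, had 6 genes in DDX41-ADARcd against the empty vector, 8 for ADARcd alone and 25 against ADARcd alone. Their median level was 1.69% in ADARcd alone, at percentile 99.0 of depth-matched random sets with a median of 1.08%, 8.33% in DDX41-ADARcd against ADARcd alone, at percentile 93.2, and 1.68% in DDX41-ADARcd against the empty vector, at percentile 60.1 with a random median of 1.62%. SPN carried 20 of the 28 sites of DDX41-ADARcd and 23 of the 41 of ADARcd alone, so the median of ADARcd alone rests largely on that gene. Monocyte and macrophage markers had 20, 21 and 30 genes, with SRGN, LCP1, LYZ and AZU1 carrying most sites against the empty vector. Histone genes had 10, 13 and 11 genes, HIST1H1C and H2AFZ among them. Mitochondrially encoded genes had 12, 13 and 12, led by ND4, ND5 and COX1. Markers of other cell types had 0, 1 (VIM) and 3 (CD4, NEFH and VIM), each site on 1 edited read. In these 5 lists no site passed a test, by either adjustment. Over all lists, 4 of 37 percentiles lay outside the central 95% of the random sets, where chance alone gives 1.85. In ADARcd alone they were those of endogenous A-to-I substrates and, on the low side, of DExD/H helicases at 2.06. In DDX41-ADARcd against ADARcd alone they were those of histone genes at 98.2 and of cytosolic ribosomal proteins, whose depth the random sets did not match. Histone genes had a median of 175 reads a site against 259 in the random sets, and the helicases 156 against 127.5. Lower depth raises the level of a site with 1 edited read, so both differences go the way of the percentile. For the endogenous A-to-I substrates, with 127 reads against 108, the difference goes the other way.

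Sites near snoRNA genes were compared because DDX41 is studied for snoRNA processing. Within 500 bases of an annotated snoRNA lay 5.18% of the sites of DDX41-ADARcd against the empty vector (4.47 to 5.96), 5.01% of those of ADARcd alone (4.48 to 5.57) and 1.73% of those of DDX41-ADARcd against ADARcd alone (1.49 to 1.999). The first 2 intervals overlap, but no test compared the shares, and clustered sites are not independent. Sites within 500 bases had a median of 588.5, 798 and 521 reads in the first library, in the same order. Over each whole list the median was 220, 286 and 30 reads, so the shares cannot be told apart from an effect of depth. Inside a snoRNA or scaRNA lay 12, 22 and 10 sites. SCARNA21, a Cajal body RNA within CHD3, was edited in 7 of 167 reads in DDX41-ADARcd (4.19%, 1.70 to 8.45) and 6 of 174 in ADARcd alone (3.45%, 1.28 to 7.35). Introns that hold a snoRNA had 1.31% (0.959 to 1.74), 1.45% (1.17 to 1.77) and 0.461% (0.34 to 0.611) of the sites.

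Coding exons held most sites: 72.8% for DDX41-ADARcd against the empty vector, 72.2% for ADARcd alone and 57.9% for DDX41-ADARcd against ADARcd alone. The 3′ UTR held 17.7% (16.5 to 19.02), 20.5% (19.5 to 21.5) and 28.3% (27.4 to 29.2), and introns 2.84%, 2.04% and 7.65%. Among sites of 10% or more with 2 or more edited reads in ADARcd alone, such as those in PKM, PGK1 and SSR2, 54.4% of 57 (40.7 to 67.6) lay in a 3′ UTR. The list against ADARcd alone reached genes of lower depth: its 7293 sites absent from the list against the empty vector had a median of 18 reads in DDX41-ADARcd, and the 3114 in both lists had 204.5.

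The base before the edited A differed with the number of edited reads. U (T in the reference) stood before 44.9% (38.7 to 51.2) of the 256 sites with 5 or more edited reads in ADARcd alone, against 16.5% of other A of the same transcripts, and G stood before 4.30% (2.16 to 7.56) against 25.7%. Among sites with 1 edited read, U stood before 15.2% (14.2 to 16.3) in ADARcd alone, 13.3% (12.6 to 14.1) in DDX41-ADARcd against ADARcd alone and 12.1% (10.9 to 13.4) in DDX41-ADARcd against the empty vector. With 3 or more edited reads it was 38.0% (33.8 to 42.5), 21.2% (12.9 to 31.8) and 28.8% (18.8 to 40.6).

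**Figure D4:**
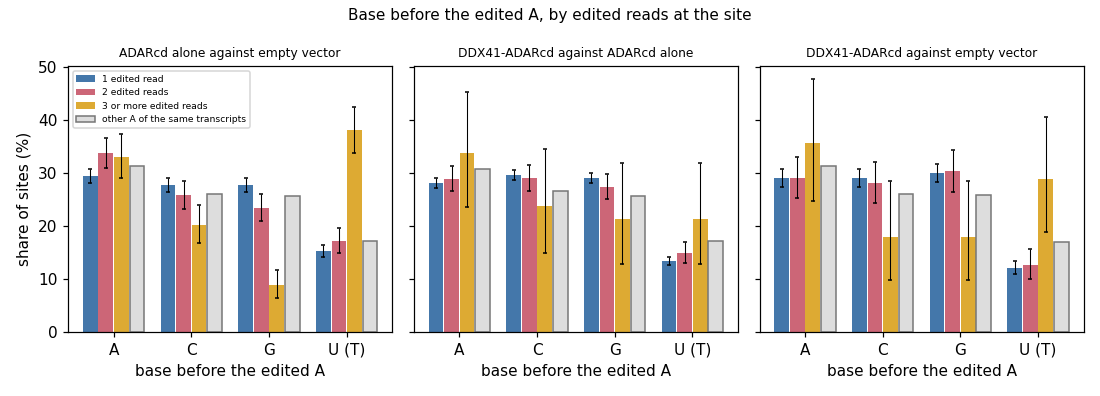
Percent of sites with each base before the edited A (U is T in the reference), by edited reads at the site, beside other A of the same transcripts, with exact 95% intervals. In ADARcd alone, U stands before 15.2% of sites with 1 edited read and 38.0% of those with 3 or more.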

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

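The tests of whether read depth, exchanged labels or less RNA of the editing domain account for lower editing in DDX41-ADARcd were chosen after that result was seen, and the others in this part before it.

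EEF1A1 carried reads with a base other than A or G in DDX41-ADARcd at position 73519168 of chromosome 6, 23 of 1641 reads (1.402%, 0.891 to 2.10), and 0 of 2310 in ADARcd alone, a floor of 0.13%. It stood out because it is a signal outside the A and G reads that the comparisons use, above the level of the control library (adjusted p 1.35e-05, Fisher's exact test). It was the only one of 8827 positions that was higher in DDX41-ADARcd than in ADARcd alone, and no position was higher in the 6412 and 3512 positions of the other 2 lists, while 1 was lower in ADARcd alone than in the empty vector.

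Most listed sites rest on 1 edited read, in genes such as ACTB, CAP1 and MALAT1. Errors of base calling, library preparation or alignment may account for most of these: the weight of the base context of strong ADARcd sites was 0.0111 (3.28e-06 to 0.0479) for DDX41-ADARcd against the empty vector, 0.0303 (0.00523 to 0.0536) against ADARcd alone and 0.112 (0.0741 to 0.152) for ADARcd alone. A weight above 0.5 would have spoken against it. The test assumes that the fusion keeps the base preference of ADARcd alone. G stood after 35.8% to 38.4% of these sites, between other A (28.0% to 28.5%) and ADARcd sites with 5 or more edited reads (55.1%). U stood before 12.1% to 15.2% of them, below both other A (16.9% to 17.1%) and those ADARcd sites (44.9%). The base after and the base before thus point apart, so the low weight does not settle whether errors made these sites. Editing by DDX41-ADARcd with another base preference stays open and was not tested.

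Sites in 20 genes, FTL, RPS3A and EEF1A1 among them, had lower editing in DDX41-ADARcd than in ADARcd alone. Lower depth was examined at the 37 shared sites chosen by their reads in ADARcd alone, which also needed an edited read in DDX41-ADARcd. Their median fold in level, 9.09 (4.03 to 14.5), lies above the largest fold in depth, 2.48. That median was taken after the 25th percentile, 1.74, had been seen. The sites up to that percentile lie in SPN, RPL7L1, RARS and HLA-B, outside the 20 genes. These folds cannot decide on depth. Choosing sites by a high level in ADARcd alone raises the fold, and a percent level does not scale with depth. Fisher's exact test does take the reads of both libraries at each site into account. Exchanged labels are argued against, since the lowest DDX41 read ratio, 3.59, lies above the 95th percentile of genes, 0.876. Less RNA of the editing domain cannot be told apart from other causes: if the domain is that of ADARB1, which only its read depth points to, its depth relative to other genes was 0.329 (0.301 to 0.375), while for ADAR the ratio was 0.714 against a gene median of 0.659, and how the domain's RNA relates to editing was not measured. An effect of the DDX41 part on where or how strongly the domain edits, the difference that the design names, stays open as untested.

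The sites of DDX41-ADARcd against the empty vector with a level of 10% or more and 2 or more edited reads, such as those in RARS, SPN, RPL7L1 and HLA-B, could be editing that the cells already had and that a shallow control missed. Of these 8 sites, 87.5% (47.3 to 99.7) lay at or within 50 bases of a site of ADARcd alone, the exception being ZKSCAN1 with 2 of 8 reads. Editing by the domain in both transduced libraries would give the same nearness, so these cannot be told apart by it, and several of the 8 sites lie in the same clusters of SPN and RPL7L1. The empty vector had 0 of 10 reads edited at RARS (unadjusted p 0.000391, adjusted p 1), but every listed site was selected for 0 edited reads in the control.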

How the results depend on the processing

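The alternatives with 3 or more edited reads, and with 5 or more in ADARcd alone at shared sites, were chosen after seeing the data; all others were planned. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Values for the 3 lists stand in the order ADARcd alone, DDX41-ADARcd against ADARcd alone, DDX41-ADARcd against the empty vector. For the settings below that reduce a list, the fall in sites follows from the filter, and the cause of other moves was not tested.

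With at least 20 reads in each library the lists held 3959, 6441 and 2258 sites with median levels of 0.226%, 1.64% and 0.267%, and with at least 50 reads 2187, 3829 and 1288 sites at 0.128%, 0.735% and 0.158%. A level of 10% or more left 58, 2237 and 11 sites at 14.9%, 14.3% and 16.9%, and of 20% or more 19, 766 and 4 sites at 29.6%, 25% and 29.2%. With 5 or more edited reads there were 260, 8 and 30 sites at 3.01%, 28.9% and 3.68%. Without mitochondrial sites the median was 0.457% for ADARcd alone and 0.552% for DDX41-ADARcd against the empty vector.

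Sites shared by DDX41-ADARcd and ADARcd alone, each against the empty vector, numbered 205 at 50 reads, 7 at 10%, 2 at 20%, 24 with 5 or more edited reads and 2040 within 50 bases. Sites shared by the 2 lists of DDX41-ADARcd numbered 1961 at 20 reads in each library, 1961 at 20 reads in all 3 libraries, 1083 at 50 reads, 3 at 10%, 1 at 20% and 0 with 5 or more edited reads. The difference at shared sites was -2.89 points with 5 or more edited reads in ADARcd alone.

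The 26 lower sites of DDX41-ADARcd against ADARcd alone became 20 with Bonferroni adjustment and 19 with reads halved, both within 1.5 times that count, and the 0 sites of DDX41-ADARcd against the empty vector stayed 0. For ADARcd alone against the empty vector the 13 sites became 6 with reads halved, which removes reads by construction. Over the named sites and alternatives, 229 values kept their side of the threshold, 23 no longer passed it and 0 reversed. Of the values that answer a comparison, 47 stayed within their limits, and 60 moved under settings fixed in advance and 12 under those added.

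Gene lists with a higher share for DDX41-ADARcd against the empty vector than for ADARcd alone numbered 10 of 13, and 4 with 3 or more edited reads (52 genes). Against the list of DDX41-ADARcd and ADARcd alone they numbered 12, and 6 among genes not listed for ADARcd alone and 4 with 3 or more edited reads. The subset of genes not listed for ADARcd alone gives no value for the comparison with that list.

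Sites near snoRNAs made up 1.08%, 0.317% and 1.11% within 100 bases, 8.87%, 3.07% and 9.16% within 2000 bases, and 7.02%, 3.77% and 6.17% with 3 or more edited reads. The 3′ UTR share was 24.8%, 30.4% and 21.0% with all overlapping regions, 15.9%, 22.5% and 13.1% at 20 reads, and 29.04%, 44.3% and 30.9% with 3 or more edited reads. U before the edited A stood at 66.7%, 18.4% and 0% (2 sites) at a level of 20% or more, and at 38.0%, 21.2% and 28.8% with 3 or more edited reads, against 17.4%, 13.6% and 12.5% of all sites. The setting with no edited read in the control moves nothing, as every listed site meets it. At the median depths, an unadjusted p under 0.05 needs levels of 13.6%, 13.3% and 12.7%.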

Other observations

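The stretches, clusters and sites in this part were chosen after their values were seen, and the Fisher's exact test of DDX41-ADARcd against ADARcd alone was fixed in advance.

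Listed sites were dense in a stretch of chromosome 1 from position 40000000 to 40999999, which held 247 sites of ADARcd alone (3.85%, 3.39 to 4.35), 285 of DDX41-ADARcd against ADARcd alone (2.74%, 2.43 to 3.07) and 150 of DDX41-ADARcd against the empty vector (4.27%, 3.62 to 4.99). CAP1, of the actin cytoskeleton, had 90 of the sites of ADARcd alone and PPT1, a lysosomal thioesterase, had 60. NFYC, a subunit of a CCAAT-binding transcription factor, had 58 sites of DDX41-ADARcd against ADARcd alone. TRIT1, a tRNA-modifying enzyme in the next stretch, had 42. Few of the sites in the first stretch had 3 or more edited reads: 17, 5 and 1 in the 3 lists. Its sites had a median depth of 1020, 59 and 610 reads in the first library, against 286, 30 and 220 over each list. A site needs only 1 edited read to be listed, so deeper positions are listed more readily.

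Neighbouring listed sites were counted by the number of edited reads. The classes were not matched on depth, and deeper positions are listed more readily, so these shares do not separate editing from depth. In DDX41-ADARcd against ADARcd alone, 67.0% (57.2 to 75.8) of sites with 3 or more edited reads had another listed site within 50 bases, against 24.4% (23.5 to 25.3) of sites with 1. In DDX41-ADARcd against the empty vector the shares were 75.3% (64.5 to 84.2) and 42.9% (41.0 to 44.7), and in ADARcd alone 66.1% (61.8 to 70.2) and 53.2% (51.8 to 54.6). SPN had 6 sites with 5 or more edited reads between positions 29665184 and 29665325 of chromosome 16 in DDX41-ADARcd, with levels from 6.38% to 16.9%, and from 9.49% to 24.2% in ADARcd alone. The mitochondrial ND4, a subunit of respiratory complex I, had 3 such sites between positions 10943 and 10946, with levels of 0.847% to 0.938% in DDX41-ADARcd and 0.386% to 1.41% in ADARcd alone.

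Of the 37 strong ADARcd sites also listed for DDX41-ADARcd, 3 were higher in DDX41-ADARcd: RARS (67.9% against 63.9%), RPL7L1 at position 42888380 of chromosome 6 (17.0% against 14.1%) and HLA-B (13.0% against 12.9%). None of the 3 passed the test, with adjusted p of 0.885, 0.71 and 1.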
